A study of Mus musculus with 20 samples.

How the data were processed

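Gene expression was measured by RNA sequencing in 20 mouse samples: 3 libraries each of C12, ih_CTC, ih_DCTC, ih_BCTC, ih_STC_BM and MDSC, and 2 of MSC. RNA was extracted with TRIzol, and libraries were made with a TruSeq RNA kit, per the labels. The deposited gene table holds expected counts, estimated numbers of read pairs per Ensembl gene, and 8.37% of its values were not whole. The submitters' processing notes name STAR, RSEM 1.2.26 and DESeq2 without giving their roles, and the reference genome build is not given in the sources used here. Coordinates are those of the deposited annotation, and 33460 of 42462 gene identifiers found in GENCODE M21 had identical start and end positions there. A deposited table of alignment quality gave reads, mapping rates and the share of reads in introns for each library. Groups were taken from the labels, which give no batch, date, animal or replicate number. Replicate numbers follow the order of the libraries and carry no other meaning.

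Counts were rounded and scaled with TMM in edgeR 4.0.16 under R 4.3.3, and genes were kept by filterByExpr by group (minimum count 10, minimum total count 15), which left 15779 of 43432. A quasi-likelihood negative binomial model with robust dispersion and a mean per group was fitted to all 20 libraries, and each of 8 comparisons was tested two-sided with Benjamini-Hochberg adjustment within the comparison at 0.05. The comparisons, the gene lists, the rule for naming genes and the main alternatives were chosen before the data were examined, except where a test is said to have been added later. Genes shared by C12, ih_CTC and ih_DCTC were those past the threshold in the same direction in all 3 against MDSC, set against the number that independent lists of the same sizes would share. Profile distance was the root mean square difference in log2 CPM (prior count 2) over the tested genes between a library and the mean of a precursor group. A fixed set of 29 gene lists with 390 genes, 367 of them tested, was tested with camera in limma 3.58.1 (preset correlation 0.01), with camera at an estimated correlation, and with fry.

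Genes were named by a fixed rule. For each line against its precursor group, the 4 genes with the largest rise and the 4 with the largest fall were named, among genes with an adjusted p under 0.05, a mean of at least 20 CPM in the higher group and every library of one group above every library of the other; for 3 libraries against 3, chance alone separates 10% of genes that way. Predicted or unnamed genes, pseudogenes and sex chromosome list genes were left out of these. From each list, up to 2 called members with the largest change and at least 5 CPM could be named. A panel of 12 genes was fixed for every comparison: Ptprc, Csf1r, Itgam, Itgax, Col1a1, Pdgfrb, Thy1, Olig2, Mki67, Cd274, Cdkn2a and Myc. The other 4 comparisons used 3 genes per direction and 1 per list. Some genes that met the rule are not reported here. Where a group had 0 counts, the fold is a lower bound against a floor of 3 counts summed over the group, and with 1 to 3 counts it is the ratio of CPM with a 95% counting interval. Intervals and floors cover counting error only. At total counts of 8794777 to 12400640 per library, that floor lies near 0.1 CPM over a group of 3 libraries.

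Alternatives chosen before the data were examined were RLE and upper quartile scaling, no filter on low counts, DESeq2 1.42.0, limma-voom, a fit of the compared groups only, a log2 fold change above 1 applied as a filter or tested with glmTreat, and leaving out each library in turn. For distances they were the 2000 genes of largest variance, a prior count of 0.5 and RLE. Alternatives chosen after seeing the data were the intron share as a covariate, leaving out the 5 line libraries with an intron share under 3% (C12 1, C12 2, ih_DCTC 1, ih_STC_BM 1 and ih_STC_BM 3), leaving out the long noncoding gene Yam1, summing the MDSC libraries to 1, and comparing ih_DCTC with ih_BCTC. RLE and upper quartile scaling moved the median log2 fold change of all genes by -0.10 and 0.27 in C12, -0.16 and 0.17 in ih_CTC and -0.14 and 0.22 in ih_DCTC against MDSC, by 0.11 and -0.13 in MDSC against MSC, and by 0.10 under upper quartile scaling in C12 against ih_CTC. The test was checked on simulated data with the sizes and spread of these libraries: with 3 libraries against 3, 2 of 67 genes changed 2-fold, 33 of 67 changed 4-fold and 54 of 66 changed 16-fold were called, beside 6 of 14719 unchanged genes. With 3 against 2, these counts were 4 of 67, 25 of 67 and 52 of 66, beside 2 of 14807. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used for tables and figures. All 20 libraries were used, and no statistic of the submitters' own was used here.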

Results

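RNA from 20 mouse cell samples was sequenced, in 7 groups that the labels name. Glioma is a tumour of the brain's supporting cells, and SU3 is a human glioma stem cell line that was grown in nude mice or beside mouse cells. The study asked what became of the host's own cells beside such a tumour, and its labels call 5 of the groups malignantly transformed. C12 (3 libraries) carried the label of macrophages transformed in culture beside SU3 peritoneal washing cells. ih_CTC (3) carried that of macrophages from a peritoneal xenograft, and ih_DCTC (3) that of bone marrow dendritic cells cultured with SU3. ih_STC_BM (3) carried the label of mesenchymal stem cells recultured from a tumour in a mouse whose bone marrow had been damaged and reconstructed. ih_BCTC (3) carried that of oligodendrocytes recultured from a brain tumour. The groups the study calls precursors were MDSC (3), myeloid cells that restrain immune responses, and MSC (2), normal bone marrow mesenchymal stem cells. The labels give DMEM with 10% fetal bovine serum as the medium. Total expected counts per library ranged from 8794777 to 12400640. Of the reads of each library, 67.4% to 77% were mapped. Levels below are TMM-scaled CPM, counts set relative to the library total, given as mean ± SD over the 3 libraries of a group, or 2 for MSC. The share of reads in introns differed between and within groups: 9.64% to 10.4% in MDSC, 2.07% and 3.09% in MSC, and 1.02% to 8.52% in the lines.

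Comparing each line with a group the study calls a precursor asks which genes differ between them. Lines labelled as macrophages or dendritic cells were set against MDSC, which are myeloid but not the labelled cell type. Of 43432 genes, 15779 had counts enough to be tested, with 13 residual degrees of freedom in a fit of all 20 libraries. C12 differed from MDSC in 9742 genes, ih_CTC from MDSC in 8723 and ih_DCTC from MDSC in 9350, and ih_STC_BM differed from MSC in 5066, by edgeR at an adjusted p under 0.05. Changes larger than 1 on the log2 scale accounted for 8892, 7861, 8431 and 4665 of these. Nothing in the labels says whether libraries of a group were separate cultures or animals, so the p-values measure only the spread between these libraries. The 3 MDSC libraries lay closer to each other than those of any other group, at profile distances of 0.413 to 0.417, against group means of 0.585 to 1.30 within the lines.

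**Figure D1:**
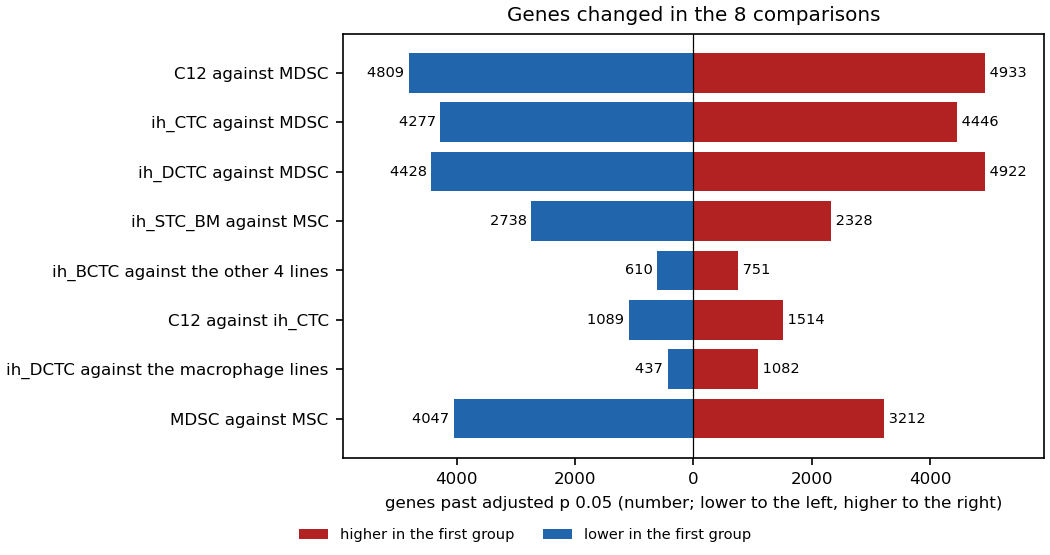
Genes higher (to the right) and lower (to the left) in the first-named group of each comparison, as numbers of genes past an adjusted p of 0.05 by edgeR. C12 against MDSC had 4933 higher and 4809 lower genes, and ih_BCTC against the other 4 lines had 751 and 610.

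Macrophages, many but not all of which descend from bone marrow myeloid cells, carry the common leukocyte antigen CD45, encoded by Ptprc. They present antigen through MHC class II molecules and depend on the CSF1 receptor. The C12 comparison with MDSC asked how far a macrophage-labelled line from co-culture still resembled a myeloid cell. C12 had 4933 genes higher and 4809 lower than MDSC. Ptprc (ENSMUSG00000026395, chromosome 1, 138062861 to 138175708) was at 0.758 ± 0.378 CPM in C12 and 1556 ± 28.9 in MDSC, a log2 fold change of -10.94 ± 0.43 (SE; edgeR adjusted p = 1.2e-11). In the pan-leukocyte list, 16 of 16 genes were lower (16 adjusted over the list alone), camera adjusted p = 3.9e-10, and the summed level of its genes was 103 ± 21.4 CPM against 9584 ± 76.7. Cd52 was 2464-fold (95% counting interval 843 to 11950.2) lower in C12. In the macrophage and monocyte list, 19 of 20 genes were lower (19 adjusted over the list alone), camera adjusted p = 6.8e-09. The chemokine receptor gene Ccr2 and the costimulatory gene Cd86 had 0 counts in C12 and were at least 1535-fold and 808-fold lower. Csf1r was at 4.53 ± 0.502 CPM against 221 ± 2.21, and the integrin gene Itgam at 0.471 ± 0.175 against 851 ± 11.8, log2 fold changes of -5.61 and -10.82. H2-Aa and H2-Eb1, MHC class II chains, had log2 fold changes of -13.23 and -11.17, and 8 of 8 class II genes were lower (8 adjusted over the list alone), camera adjusted p = 5.4e-06. In the dendritic cell list, 1 of 14 genes were higher and 11 lower (1 and 11 adjusted over the list alone), camera adjusted p = 7.1e-04, adjusted p = 0.0642 with an estimated correlation. Cd83 was at a log2 fold change of -10.80 and Itgax 1289.6-fold (95% interval 231 to 50981) lower. These genes had an edgeR adjusted p of at most 2.3e-06.

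By the naming rule the lowest genes of C12 against MDSC were Olfm4 (ENSMUSG00000022026, chromosome 14, 80000302 to 80021930), a secreted protein of neutrophils, and the immunoglobulin segment gene Ighv2-6 (ENSMUSG00000096670, chromosome 12, 113716670 to 113717103). Both had 0 counts in C12 and 317 ± 3.83 and 305 ± 3.33 CPM in MDSC, at least 3272-fold and 3151-fold lower. Clec7a, which encodes a receptor for fungal glucans (ENSMUSG00000079293, a symbol that another gene shares), and BC100530 followed, at least 2804-fold and 2754-fold lower. Ighv2-6 and BC100530 have near copies that share reads, so their values are uncertain. All 18 granulocyte genes were lower (18 adjusted over the list alone), camera adjusted p = 1.0e-11. The granule gene Ngp was at a log2 fold change of -12.89 and Il1b 20497-fold (95% interval 3678 to 809617) lower. All 8 erythroid and all 12 lymphocyte genes were lower as well (8 and 12 adjusted over the list alone), camera adjusted p = 4.1e-07 and 4.8e-09, and with the intron share as a covariate lymphocyte genes were 0 higher and 6 lower. Those falls rest on the MDSC libraries, at summed levels of 15763 ± 459.5 and 1480.3 ± 32.3 CPM. Class II falls may too: sums were 7832 ± 197 CPM in MDSC but 139 ± 16 in MSC, richer in macrophage transcripts. MHC class I genes were lower in 8 of 12 (8 adjusted over the list alone), camera adjusted p = 0.0261, adjusted p = 0.411 with an estimated correlation. H2-K1 was at 31.4 ± 8.0 CPM against 798 ± 21.3 and Nlrc5, which activates class I genes, at 6.6 ± 4.16 against 100 ± 0.593. These genes had an edgeR adjusted p of at most 5.6e-05.

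Fibroblasts and their mesenchymal relatives make fibrillar collagen, the main protein of connective tissue, and depend on transcription factors such as Snai2 and Twist2. Col1a1 (ENSMUSG00000001506, chromosome 11, 94936224 to 94953042), a type I collagen chain, was at 2205 ± 405 CPM in C12 and 2.51 ± 0.223 in MDSC, a log2 fold change of 9.77 ± 0.68 (SE; edgeR adjusted p = 2.7e-09). Its partner Col1a2 was at 4939.9 ± 1399.8 against 4.84 ± 0.603 CPM (edgeR adjusted p = 2.8e-10). In the fibroblast and extracellular matrix list, 17 of 20 genes were higher and 2 lower (17 and 2 adjusted over the list alone), camera adjusted p = 1.1e-06, adjusted p = 0.317 with an estimated correlation. In the list of mesenchymal transcription factors and cadherins, 8 of 11 genes were higher and 1 lower (8 and 1 adjusted over the list alone), camera adjusted p = 0.00468, and 5 higher and 0 lower with the intron share as a covariate. Snai2 had 0 counts in MDSC and was at least 348-fold higher, and Twist2 was 553-fold (95% interval 189 to 2685) higher. Mesenchymal stem cell genes were 8 higher and 5 lower of 18 (9 and 5 adjusted over the list alone), camera adjusted p = 0.119, and 10 higher and 1 lower with it. Pdgfra and Grem1 were at log2 fold changes of 8.25 and 8.03 and the pericyte receptor gene Pdgfrb at 6.16. The highest genes were Dclk1 (ENSMUSG00000027797, chromosome 3, 55242526 to 55539064), a kinase related to doublecortin, Aldh3a1, an aldehyde dehydrogenase, the water channel gene Aqp5 and Igf2bp1, an RNA-binding protein of embryonic tissue. Dclk1 and Igf2bp1 had 0 counts in MDSC and were at least 895-fold and 473-fold higher, Aldh3a1 rose to 3283 ± 2177 from 0.555 ± 0.207 CPM, and Aqp5 was 6032-fold (95% interval 1669.6 to 49815) higher. The edgeR adjusted p of these genes was at most 5.7e-06.

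Dividing cells raise genes of DNA replication and mitosis, and many tumour cells run glycolysis at a high rate. Glycolysis and hypoxia genes were 10 higher and 0 lower of 14 (10 and 0 adjusted over the list alone) in C12 against MDSC, camera adjusted p = 0.0294, adjusted p = 0.559 with an estimated correlation. Tpi1 and Eno1 were at log2 fold changes of 2.96 and 2.76 (edgeR adjusted p at most 5.7e-04). These genes also moved with the share of reads in introns: over the 15 line libraries 10 of 14 fell as that share rose, and with the share as a covariate the count was 0 higher and 4 lower. Tpi1 and Eno1 then changed sign, to -0.40 and -0.12. The share was 1.02% to 5.23% in C12 and 9.64% to 10.4% in MDSC, without overlap, so these adjusted values extrapolate. Oxidative phosphorylation genes were 8 higher and 0 lower of 13 (8 and 0 adjusted over the list alone), camera adjusted p = 0.0817, and 0 higher and 2 lower with the covariate. Cell cycle genes were 3 higher and 2 lower of 22 (0 and 1 adjusted over the list alone), camera adjusted p = 0.976, and 0 higher and 7 lower with the covariate. Mki67, a marker of proliferation, was at 77.7 ± 36.2 CPM in C12 against 842 ± 16 in MDSC (edgeR adjusted p = 0.00179), and the call of Mki67 in C12 against MDSC ended with the covariate, its log2 fold change going from -3.44 to -1.14 (adjusted p = 0.452). Plk1, a mitotic kinase gene, was higher at 111 ± 82.9 against 35.9 ± 2.43 CPM (edgeR adjusted p = 0.0438). The call of Plk1 in C12 against MDSC ended without C12 1, C12 2, MDSC 1, MDSC 2 or MDSC 3, with an adjusted p from 0.0889 to 0.211, and its log2 fold change of 1.63 turned to -0.50 with the covariate. Myc did not pass, at 209.7 ± 98.1 against 327 ± 10.8 CPM (edgeR adjusted p = 0.234).

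A tumour in the peritoneum is surrounded by macrophages of the host. The ih_CTC line, labelled as macrophages transformed in such a xenograft, was compared with MDSC as its myeloid precursor. It had 4446 genes higher and 4277 lower. Ptprc was at 0.236 ± 0.0651 CPM in ih_CTC and 1556 ± 28.9 in MDSC, a log2 fold change of -12.63 ± 0.47 (SE; edgeR adjusted p = 5.9e-12). All 16 pan-leukocyte genes were lower (16 adjusted over the list alone), camera adjusted p = 3.3e-12, among them the lymphoid regulator Ikzf1, 5774-fold (95% interval 1975 to 28003) lower. All 20 macrophage and monocyte genes were lower (20 adjusted over the list alone), camera adjusted p = 9.5e-10. Itgam was at a log2 fold change of -11.95, Csf1r at -6.38 and Ccr2 5103-fold (95% interval 915 to 201595) lower. All 8 MHC class II genes were lower (8 adjusted over the list alone), camera adjusted p = 7.3e-07. H2-Aa was at a log2 fold change of -13.07 and the invariant chain gene Cd74 at -12.68. Dendritic cell genes were 1 higher and 10 lower of 14 (1 and 10 adjusted over the list alone), camera adjusted p = 3.7e-04, adjusted p = 0.0507 with an estimated correlation. Irf8 was at a log2 fold change of -10.21 and Cd83 10776-fold (95% interval 2983 to 88991) lower. MHC class I genes were 0 higher and 10 lower of 12 (0 and 10 adjusted over the list alone), camera adjusted p = 5.7e-04, adjusted p = 0.185 with an estimated correlation. Nlrc5 and H2-K1 were at log2 fold changes of -5.24 and -4.96. These genes had an edgeR adjusted p of at most 5.1e-06.

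By the naming rule the lowest genes of ih_CTC included the beta-globin gene Hbb-bt (ENSMUSG00000073940, chromosome 7, 103812524 to 103813996), the cytokine gene Osm and the immunoglobulin gene Iglv1, each with 0 counts in ih_CTC. They were at least 9419-fold, 2998-fold and 2371-fold lower, and Hbb-bt and Iglv1 have near copies that share reads. All 18 granulocyte, 12 lymphocyte and 8 erythroid genes were lower (18, 12 and 8 adjusted over the list alone), camera adjusted p = 4.4e-13, 9.8e-10 and 7.9e-08. Retnlg, a resistin-like gene of granulocytes, fell to 0.142 ± 0.089 from 1425 ± 61.7 CPM, and Ly6c2 was 11419-fold (95% interval 3161 to 94299) lower. The highest genes were Fez1 (ENSMUSG00000032118, chromosome 9, 36821939 to 36878924), linked to axon growth, Dclk1, the cyclic-GMP kinase gene Prkg2 and Igf2bp1. All had 0 counts in MDSC and were at least 609-fold, 599-fold, 554-fold and 502-fold higher. Matrix genes were 17 higher and 1 lower of 20 (17 and 2 adjusted over the list alone), camera adjusted p = 1.1e-07, adjusted p = 0.185 with an estimated correlation. Col1a1 was at 1569 ± 106 CPM against 2.51 ± 0.223, the crosslinking enzyme gene Lox at 1652 ± 399.9 against 1.33 ± 0.442 and Col3a1 at 1081 ± 61.8 against 1.09 ± 0.128. Mesenchymal stem cell genes were 9 higher and 2 lower of 18 (9 and 4 adjusted over the list alone), camera adjusted p = 0.0353, adjusted p = 0.455 with an estimated correlation. Grem1, Prrx1 and Pdgfrb were at log2 fold changes of 10.34, 10.05 and 6.0. The list of mesenchymal transcription factors and cadherins had 8 higher and 0 lower of 11 (9 and 0 adjusted over the list alone), camera adjusted p = 5.0e-04. Snai2 was at least 466-fold and Twist2 1044-fold (95% interval 357 to 5066) higher. Glycolysis genes were 9 higher and 0 lower of 14 (9 and 0 adjusted over the list alone), camera adjusted p = 0.0112, adjusted p = 0.483 with an estimated correlation, and 7 higher and 1 lower with the intron share as a covariate; Bnip3 and Tpi1 had log2 fold changes of 3.96 and 2.92. The surface protein gene Thy1 rose to 50.5 ± 14.9 from 12.1 ± 1.36 CPM, while Mki67 and Myc did not pass (edgeR adjusted p = 0.10 and 0.852). For the genes that passed the edgeR adjusted p was at most 0.00886.

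Dendritic cells carry antigen from tissue to T cells and are marked by the integrin Itgax, MHC class II and the factor Irf8. The ih_DCTC line, labelled as such cells transformed in culture, was compared with MDSC. It had 4922 genes higher and 4428 lower. Dendritic cell genes were 2 higher and 9 lower of 14 (2 and 9 adjusted over the list alone), camera adjusted p = 0.00255, adjusted p = 0.0972 with an estimated correlation. Cd83, a marker of mature dendritic cells, was at 0.359 ± 0.322 CPM against 628 ± 9.66 in MDSC, and Irf8 at 0.229 ± 0.145 against 255 ± 16.6. Itgax was 673-fold (95% interval 186 to 5567) lower. All 8 MHC class II genes were lower (8 adjusted over the list alone), camera adjusted p = 1.4e-06. H2-Aa was 14571-fold (95% interval 4986 to 70660.1) and H2-Eb1 9149-fold (95% interval 3130.2 to 44367) lower. MHC class I genes were 0 higher and 10 lower of 12 (0 and 10 adjusted over the list alone), camera adjusted p = 0.00278, adjusted p = 0.303 with an estimated correlation. Nlrc5 and H2-K1 were at log2 fold changes of -4.27 and -3.84. Ptprc was at 0.341 ± 0.0593 CPM, a log2 fold change of -12.11 ± 0.46 (SE; edgeR adjusted p = 7.5e-12). All 16 pan-leukocyte genes were lower (16 adjusted over the list alone), camera adjusted p = 5.7e-12. The GTPase gene Rac2 was at a log2 fold change of -12.59 and its activator Vav1 7454-fold (95% interval 1337 to 294465) lower. Macrophage and monocyte genes were 0 higher and 17 lower of 20 (0 and 17 adjusted over the list alone), camera adjusted p = 3.7e-09. Cd86 was at least 844-fold lower and Itgam and Csf1r at log2 fold changes of -11.83 and -6.79. Pdgfrb was higher at 5.44, while Myc did not pass (edgeR adjusted p = 0.953). For the genes that passed the edgeR adjusted p was at most 2.7e-05.

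By the naming rule the lowest genes of ih_DCTC included the B cell receptor gene Cd22 (ENSMUSG00000030577, chromosome 7, 30865402 to 30880342), the haem synthesis gene Alas2 of red cells, and the myeloid receptor gene Cd300lf. All had 0 counts in ih_DCTC and were at least 4386-fold, 4246-fold and 3622-fold lower. All 18 granulocyte, 12 lymphocyte and 8 erythroid genes were lower (18, 12 and 8 adjusted over the list alone), camera adjusted p = 5.2e-12, 1.6e-09 and 1.6e-07, with Csf3r 21852-fold (95% interval 3921 to 863150.0) and Mmp8 17900.0-fold (95% interval 3212 to 707060.0) lower. The highest genes were the desmosome gene Pkp1 (ENSMUSG00000026413, chromosome 1, 135871395 to 135919207), Fez1, Igf2bp1 and Nlrp2, of an innate immune receptor family. All had 0 counts in MDSC and were at least 499-fold, 432-fold, 429-fold and 377-fold higher. Matrix genes were 18 higher and 1 lower of 20 (18 and 1 adjusted over the list alone), camera adjusted p = 3.6e-08, adjusted p = 0.194 with an estimated correlation. Col1a1 was at 2345 ± 269 CPM against 2.51 ± 0.223, the proteoglycan gene Dcn at 1225 ± 857 against 0.916 ± 0.618 and Col3a1 at 1274 ± 544 against 1.09 ± 0.128. The list of mesenchymal transcription factors and cadherins had 9 higher and 0 lower of 11 (9 and 1 adjusted over the list alone), camera adjusted p = 0.00161. Snai2 was at least 305-fold and Twist2 1099-fold (95% interval 376 to 5332) higher. Neuron genes were 8 higher and 0 lower of 9 (8 and 0 adjusted over the list alone), camera adjusted p = 0.00489, adjusted p = 0.0972 with an estimated correlation. The neurofilament gene Nefl was at least 129.9-fold and Stmn2, a tubulin regulator of growing axons, 1048-fold (95% interval 290.0 to 8662) higher. Sox2, a stem cell factor, was at 62.4 ± 35.3 CPM against 0.071 ± 0.123, and Nes, which encodes nestin, at 90.4 ± 51.8 against 0.293 ± 0.157, while the astrocyte and neural stem cell list had 5 higher and 3 lower of 10 (5 and 3 adjusted over the list alone), camera adjusted p = 0.463. Glycolysis genes were 13 higher and 0 lower of 14 (13 and 0 adjusted over the list alone), camera adjusted p = 8.0e-04, adjusted p = 0.418 with an estimated correlation, and 5 higher and 0 lower with the intron share as a covariate; Bnip3 and Tpi1 had log2 fold changes of 5.13 and 3.68. Cell cycle genes were 0 higher and 4 lower of 22 (0 and 3 adjusted over the list alone), camera adjusted p = 0.344, and 0 higher and 10 lower with the covariate. Mki67 was at 132 ± 160.0 CPM against 842 ± 16 and Ccnb2 at 26 ± 11.6 against 80.9 ± 3.16. All of these genes passed, with an edgeR adjusted p of at most 0.00862.

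Tumour cells can change signalling, stress and growth control, and a line may carry genes of tissues its label does not name. The remaining lists are given for C12, ih_CTC and ih_DCTC against MDSC, in that order, as genes past the edgeR threshold. Interferon response genes, which cells switch on against viruses, were 1, 0 and 1 higher and 11, 12 and 12 lower of 16 (12, 12 and 12 lower adjusted over the list alone). Their camera adjusted p was 0.00197, 0.00368 and 8.0e-04, and 0.381, 0.361 and 0.337 with an estimated correlation. Immediate early genes, which respond within minutes to handling or growth signals, were 0, 0 and 1 higher and 9, 8 and 7 lower of 10 (9, 9 and 8 lower adjusted over the list alone). Immunosuppression and checkpoint genes were 4, 4 and 6 higher and 9 lower in each line of 15, with Cd274, which encodes the checkpoint ligand PD-L1, at log2 fold changes of -6.89, -7.14 and -7.83 (edgeR adjusted p at most 2.7e-08). Oncogenes and receptor tyrosine kinases were 8, 8 and 7 higher and 4, 1 and 2 lower of 16, chemokines and growth factors 6, 7 and 7 higher and 6, 6 and 5 lower of 17, and p53 pathway and cell cycle inhibitors 7, 5 and 6 higher and 5, 5 and 4 lower of 15. Smooth muscle and myofibroblast genes were 5, 4 and 4 higher and 1, 0 and 1 lower of 9, and neuron genes 5, 7 and 8 higher and 1, 1 and 0 lower of 9. Oligodendrocyte lineage genes were 2, 1 and 2 higher and 4 lower in each line of 7, astrocyte and neural stem cell genes 4, 3 and 5 higher and 3 lower in each line of 10, and microglia genes 3 higher and 3 lower in each line of 7. Endothelial genes were 0, 0 and 1 higher and 3, 4 and 3 lower of 7, and epithelial and mesothelial genes 5, 3 and 3 higher and 1, 2 and 1 lower of 8. Mitochondrially encoded genes were 0 higher and 0 lower in each line of 10, oxidative phosphorylation genes 8, 3 and 5 higher and 0 lower in each line of 13, and sex chromosome genes 0, 2 and 0 higher and 0, 1 and 0 lower of 5. With the intron share as a covariate, p53 pathway genes were 4 higher and 0 lower, 4 higher and 1 lower, and 4 higher and 0 lower. In C12 oncogenes were then 6 higher and 1 lower and microglia genes 2 higher and 0 lower, and in ih_DCTC immediate early genes 0 higher and 4 lower, mitochondrially encoded genes 3 higher and 0 lower and oxidative phosphorylation genes 0 higher and 4 lower. Over all 8 comparisons and 29 lists, camera with the preset correlation passed 75 of 232 tests and camera with an estimated correlation 30. The calls against MDSC that held with an estimated correlation were the macrophage and monocyte, pan-leukocyte, granulocyte, MHC class II, lymphocyte and erythroid lists and the mesenchymal transcription factors and cadherins, in all 3 lines. A list's median, mean and camera direction differed in sign in 32 of the 232 tests, and in 0 of those did camera with the preset correlation pass.

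**Figure D2:**
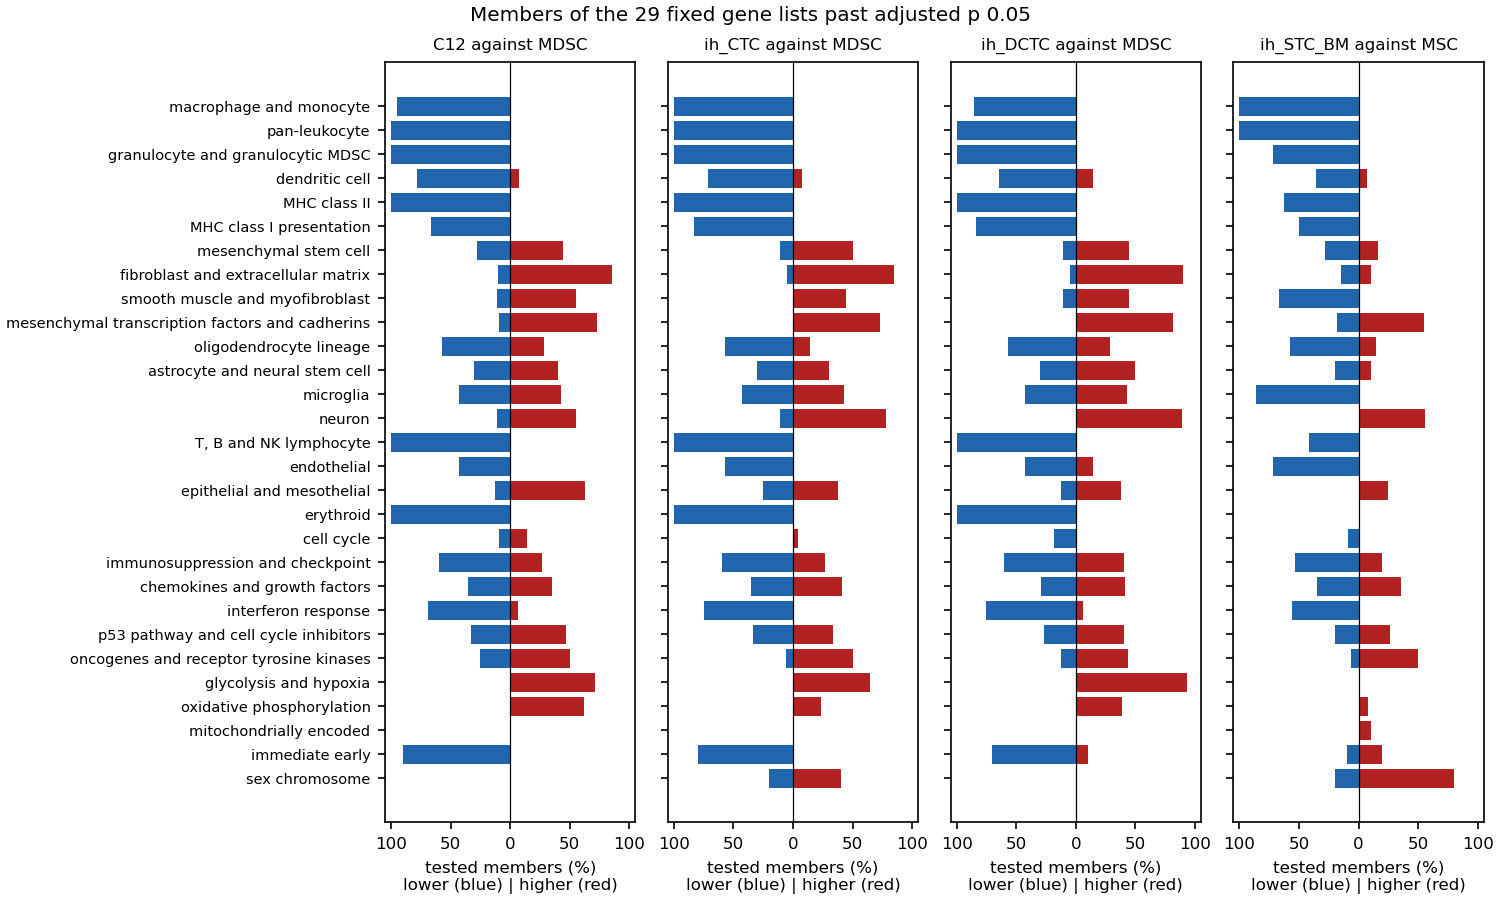
Share of the tested members of each gene list past an adjusted p of 0.05 by edgeR, in percent, lower to the left in blue and higher to the right in red, in 4 comparisons. The pan-leukocyte list had 16 of 16 tested members lower in each of the 4.

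Genes that change alike in lines of separate labelled origin may mark a common programme or only the MDSC reference. Against MDSC, 3328 genes were higher and 3379 lower in all of C12, ih_CTC and ih_DCTC, by edgeR at an adjusted p under 0.05. Independent lists of the same sizes would share 433.6 and 365.8 genes, and 20 simulations of unchanged groups shared 0 each way. The comparisons use the same 3 MDSC libraries, so their calls are not independent and excess sharing is untested. With those libraries summed to 1 genes higher in all 3 lines fell to 1912. The panel genes moved alike in the 3 lines except Thy1 and Mki67. Thy1 was 1.85 ± 0.0366 CPM in C12, 1.88 ± 2.61 in ih_DCTC and 50.5 ± 14.9 in ih_CTC, against 12.1 ± 1.36 in MDSC. Thy1 passed as lower in C12 and ih_DCTC and as higher in ih_CTC (edgeR adjusted p at most 0.00886). Mki67 passed as lower in C12 and ih_DCTC but not in ih_CTC, and its difference between C12 and ih_CTC did not pass either (edgeR adjusted p = 0.106). With the intron share as a covariate, the calls of Thy1 in C12 against MDSC, Thy1 in ih_DCTC against MDSC and Mki67 in ih_DCTC against MDSC ended, like that of Mki67 in C12 above (adjusted p = 0.335, 0.142 and 0.297), with log2 fold changes going from -2.71, -2.66 and -2.68 to -1.67, -1.90 and -1.16. That of Thy1 in ih_CTC against MDSC ended with the MDSC libraries summed to 1 (adjusted p = 0.155, log2 fold change from 2.06 to 1.96), while Thy1 in C12 against ih_CTC passed in all 16 alternatives tried. Mki67 in ih_CTC against MDSC passed with DESeq2 and in a fit of those groups (adjusted p = 0.0366 and 1.5e-04). Cdkn2a, which encodes the cell cycle inhibitors p16 and p19, had 0 counts in the 3 lines and 0.231 ± 0.20 CPM in MDSC, and the oligodendrocyte factor gene Olig2 had too few counts to test. The calls of Cdkn2a in C12 against MDSC, Cdkn2a in ih_CTC against MDSC and Cdkn2a in ih_DCTC against MDSC (edgeR adjusted p = 0.0335, 0.0323 and 0.0331) ended without any single library of the line, MDSC 1 or MDSC 2, with an adjusted p from 0.0557 to 0.0875, and with the covariate (adjusted p = 0.601, 0.301 and 0.475).

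**Figure D3:**
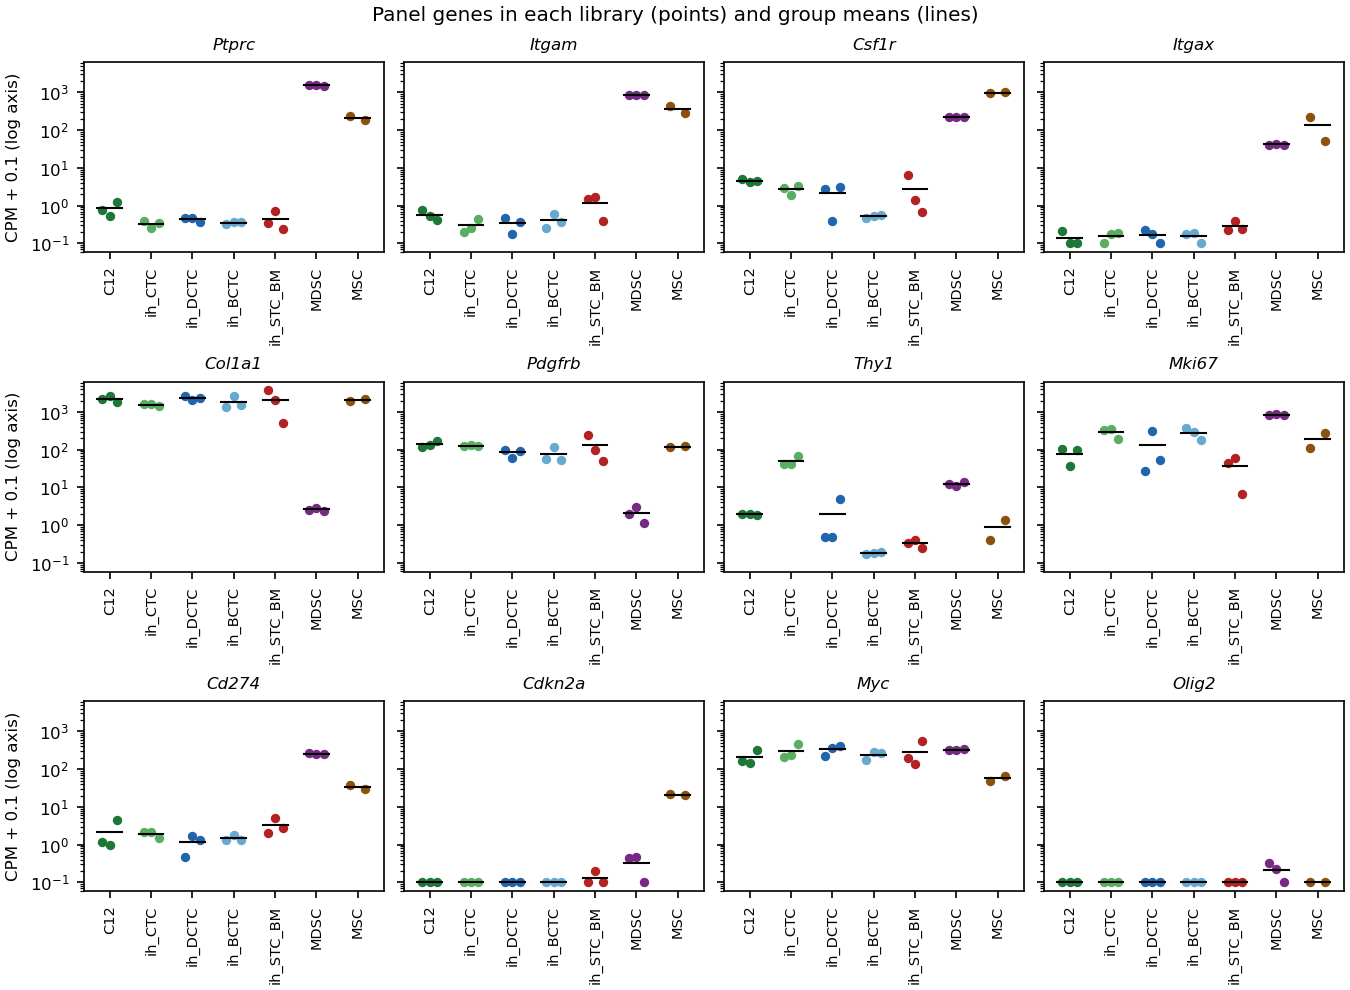
TMM-scaled CPM of the 12 panel genes plus 0.1, on a log axis, with a point per library and a line at each group's mean. Ptprc stayed near or under 1 CPM in the 15 line libraries, and Col1a1 was lowest in MDSC.

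Mesenchymal stem cells of the bone marrow form bone, fat and cartilage. The ih_STC_BM line, labelled as such cells transformed in a tumour of a mouse with reconstructed marrow, was compared with normal MSC. It had 2328 genes higher and 2738 lower, with 2 MSC libraries. The number of genes changed in ih_STC_BM against MSC fell to 3120 without MSC 1 and 3338 without MSC 2, where the lone MSC library is assumed to vary like the other groups. Col1a1 and Pdgfrb did not pass: Col1a1 was at 2077 ± 1612 CPM in ih_STC_BM and 2077 ± 182 in MSC (edgeR adjusted p = 1), and Pdgfrb at 132 ± 102 and 119 ± 4.8 (edgeR adjusted p = 0.854). Matrix genes were 2 higher and 3 lower of 20 (2 and 3 adjusted over the list alone), camera adjusted p = 0.889, with a median above and a mean below 0. Mesenchymal stem cell genes were 3 higher and 5 lower of 18 (3 and 6 adjusted over the list alone), camera adjusted p = 0.399. The adhesion gene Mcam was at a log2 fold change of -3.96 and the fat cell factor gene Pparg at -3.27. Smooth muscle genes were 0 higher and 6 lower of 9 (0 and 7 adjusted over the list alone), camera adjusted p = 9.6e-06: the smooth muscle actin gene Actg2 (ENSMUSG00000059430, chromosome 6, 83512905 to 83536265) had 0 counts and was at least 1105-fold lower, and Tagln fell to 0.454 ± 0.308 from 606 ± 126 CPM. In the list of mesenchymal transcription factors and cadherins, with 6 higher and 2 lower of 11 (6 and 2 adjusted over the list alone), camera adjusted p = 0.122, Twist2 was higher and Cdh11 lower, at log2 fold changes of 5.87 and -9.52. For the genes that passed the edgeR adjusted p was at most 9.7e-04.

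Cultures grown from bone marrow by adherence often carry macrophages beside the stromal cells. The MSC libraries held macrophage transcripts: Csf1r was at 981 ± 55.1 CPM and Adgre1, which encodes F4/80, at 617 ± 55.6, with a summed macrophage and monocyte level of 24409.5 ± 4475 CPM against 8665 ± 151 in MDSC. All 20 macrophage and monocyte genes and all 16 pan-leukocyte genes were lower in ih_STC_BM (20 and 16 adjusted over the list alone), camera adjusted p = 2.2e-20 and 1.0e-19. The complement gene C1qc, Fcer1g and Tyrobp had log2 fold changes of -10.50, -11.21 and -10.39, and Ptprc, Csf1r and Itgam of -9.19, -8.48 and -8.30. Adgre1 was 7611-fold (95% interval 2106 to 62853) lower. The lowest genes beside Actg2 were the macrophage receptor gene Fcrls (ENSMUSG00000015852, chromosome 3, 87250758 to 87263738), the complement inhibitor gene Serping1 and the leukocyte surface gene Cd48, all with 0 counts in ih_STC_BM and at least 2123-fold, 1245-fold and 821-fold lower. The highest were Xlr3a (ENSMUSG00000057836, chromosome X, 73086293 to 73097095), at least 527-fold higher and one of several near-identical X-linked copies, the mesothelial gene Msln, 6378-fold (95% interval 1144 to 251965) higher, the Notch-related gene Dlk1 at 1222 ± 1922 against 0.252 ± 0.232 CPM, and the cytidine deaminase gene Cda, at least 147-fold higher. Cdkn2a was 519.7-fold (95% interval 92.8 to 20574) lower and its neighbour Cdkn2b 791-fold (95% interval 142 to 31304) lower. Microglia genes, shared with tissue macrophages, were 0 higher and 6 lower of 7 (0 and 6 adjusted over the list alone), camera adjusted p = 3.0e-05, adjusted p = 0.0614 with an estimated correlation. P2ry12 was at least 66.5-fold lower. The edgeR adjusted p of these genes was at most 2.1e-04. Myc was higher, at 292 ± 217 against 57.7 ± 14 CPM (edgeR adjusted p = 0.00391), and the call of Myc in ih_STC_BM against MSC ended without MSC 1, with an adjusted p = 0.0624. Mki67 was lower, at 37.7 ± 28.2 against 193 ± 120.2 CPM (edgeR adjusted p = 0.0426), and the call of Mki67 in ih_STC_BM against MSC ended without ih_STC_BM 1, ih_STC_BM 3 or MSC 2, with an adjusted p from 0.0735 to 0.327. Thy1 did not pass (edgeR adjusted p = 0.221), and Cd274 and Itgax were lower at log2 fold changes of -3.37 and -9.35 (edgeR adjusted p at most 1.1e-04).

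The remaining lists were given the same tests in ih_STC_BM against MSC. Granulocyte genes were 0 higher and 13 lower of 18 (0 and 13 adjusted over the list alone), camera adjusted p = 8.8e-04, adjusted p = 0.29 with an estimated correlation. Dendritic cell genes were 1 higher and 5 lower of 14 (1 and 5 adjusted over the list alone), camera adjusted p = 0.023, adjusted p = 0.227 with an estimated correlation. Lymphocyte genes were 0 higher and 5 lower of 12 (0 and 5 adjusted over the list alone), camera adjusted p = 0.0337, adjusted p = 0.319 with an estimated correlation. MHC class II genes were 0 higher and 5 lower of 8 (1 and 5 adjusted over the list alone), camera adjusted p = 0.015, adjusted p = 0.227 with an estimated correlation. Class I genes were 0 higher and 6 lower of 12 (0 and 7 adjusted over the list alone), camera adjusted p = 0.043, adjusted p = 0.382 with an estimated correlation. Interferon response genes were 0 higher and 9 lower of 16 (0 and 9 adjusted over the list alone), camera adjusted p = 0.00683, adjusted p = 0.353 with an estimated correlation. Endothelial genes were 0 higher and 5 lower of 7 (0 and 6 adjusted over the list alone), camera adjusted p = 0.00683, adjusted p = 0.227 with an estimated correlation. Immunosuppression and checkpoint genes were 3 higher and 8 lower of 15 (3 and 8 adjusted over the list alone), camera adjusted p = 0.0337, adjusted p = 0.227 with an estimated correlation. Neuron genes were 5 higher and 0 lower of 9 (6 and 0 adjusted over the list alone), camera adjusted p = 0.023, adjusted p = 0.227 with an estimated correlation. Glycolysis genes were 0 higher and 0 lower of 14 and oxidative phosphorylation genes 1 higher and 0 lower of 13, and 7 higher and 0 lower and 6 higher and 0 lower with the intron share as a covariate, whose values were 2.34%, 8.52% and 1.79% in the 3 ih_STC_BM libraries. Without the 2 libraries of low share only ih_STC_BM 2 was left, so no counts are given. Cell cycle genes were 0 higher and 2 lower of 22, immediate early genes 2 higher and 1 lower of 10, oncogenes and receptor tyrosine kinases 8 higher and 1 lower of 16, chemokines and growth factors 6 higher and 6 lower of 17, and p53 pathway genes 4 higher and 3 lower of 15, with a mean of the other sign than the median in the last. With the covariate, cell cycle genes were 4 higher and 3 lower, oncogenes 8 higher and 4 lower and p53 pathway genes 6 higher and 6 lower. Oligodendrocyte genes were 1 higher and 4 lower of 7, astrocyte genes 1 higher and 2 lower of 10, epithelial and mesothelial genes 2 higher and 0 lower of 8, erythroid genes 0 higher and 0 lower of 8, and mitochondrially encoded genes 1 higher and 0 lower of 10. Sex chromosome genes were 4 higher and 1 lower of 5, since ih_STC_BM carried Y-linked transcripts and MSC carried Xist. The calls that held with an estimated correlation were the macrophage and monocyte, pan-leukocyte and smooth muscle lists.

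A line's whole expression profile can lie nearer to MDSC or to MSC, whatever its label says. Distances in log2 CPM, defined above, were not tested. C12 lay 2.93 ± 0.14 from MDSC and 2.05 ± 0.10 from MSC (SD, n = 3). The distance to MDSC exceeded that to MSC by 0.88 ± 0.05 in C12, 0.82 ± 0.01 in ih_CTC and 0.85 ± 0.06 in ih_DCTC. It did so by 0.89 ± 0.07 in ih_STC_BM and 0.78 ± 0.04 in ih_BCTC. All 15 line libraries lay nearer to MSC than to MDSC, and MDSC and MSC libraries lay 2.36 apart on average. Summed fibroblast and matrix levels were 13144 to 21493 CPM over the 5 lines, 15489 ± 647 in MSC and 1621 ± 41.3 in MDSC. Summed pan-leukocyte levels were 7.74 to 103 CPM over the 5 lines, 6823 ± 1729 in MSC and 9584 ± 76.7 in MDSC.

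**Figure D4:**
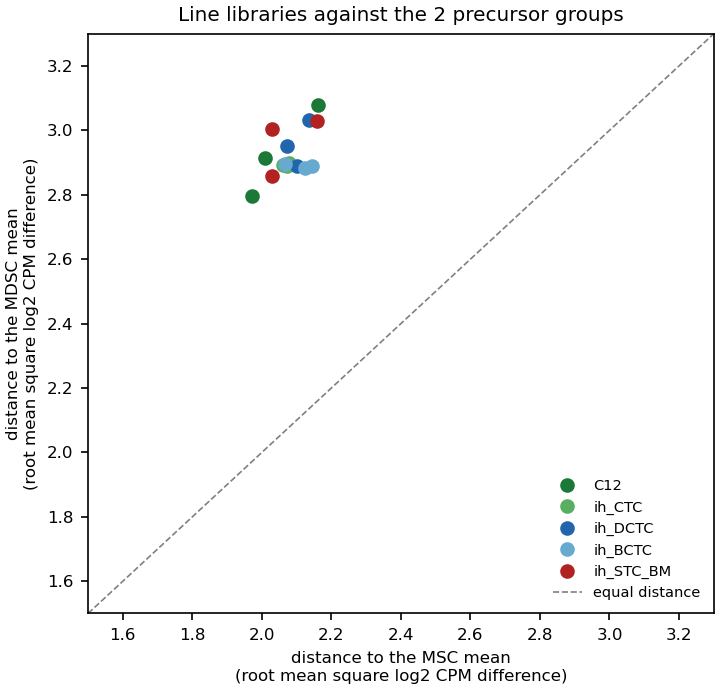
Distance of each of the 15 line libraries to the MDSC mean (vertical axis) against its distance to the MSC mean (horizontal axis), as root mean square log2 CPM differences, with a dashed line at equal distance. All 15 points lie above the line, nearer to MSC.

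Oligodendrocyte precursors express Olig2, Sox10 and Cspg4. The ih_BCTC line, labelled as transformed oligodendrocytes, has no precursor group here. It was compared with the mean of the other 4 lines, given without an SD. It had 751 genes higher and 610 lower. The number of genes changed in ih_BCTC against the other 4 lines, 1361, fell to 524, 841 and 556 without ih_BCTC 1, 2 and 3 and rose to 2047 without ih_STC_BM 2. Oligodendrocyte lineage genes were 1 higher and 1 lower of 7 (1 and 1 adjusted over the list alone), camera adjusted p = 0.991, and Olig2 had 0 counts in all 5 lines. The largest rises under the rule were the adenylyl cyclase gene Adcy8 (ENSMUSG00000022376, chromosome 15, 64699042 to 64922296), the teneurin gene Tenm3 and the translation factor gene Eif4g3, at log2 fold changes of 4.51, 4.29 and 3.99. Sox2 was at 104 ± 16.6 CPM in ih_BCTC and a mean of 17.3 over the other lines, and Stmn2 at 76.5 ± 19.5 against 24.7. Neither was particular to ih_BCTC: ih_DCTC had 62.4 ± 35.3 CPM of Sox2 and 83.9 ± 36.7 of Stmn2. The astrocyte and neural stem cell list, with Sox2, was 1 higher and 0 lower of 10 (1 and 0 adjusted over the list alone), camera adjusted p = 0.128, and the neuron list, with Stmn2, 3 higher and 0 lower of 9 (4 and 0 adjusted over the list alone), camera adjusted p = 0.0555. The largest falls included the prostacyclin synthase gene Ptgis (ENSMUSG00000017969, chromosome 2, 167191805 to 167240604) and Ugt1a7c, of a glucuronidation cluster that shares exons, at log2 fold changes of -5.74 and -4.47. Pan-leukocyte genes were 0 higher and 3 lower of 16 (0 and 3 adjusted over the list alone), camera adjusted p = 3.0e-04, adjusted p = 0.271 with an estimated correlation. Itgb2 was at 3.65 ± 1.98 against 27.6 CPM. The list summed to 7.74 CPM in ih_BCTC and 10.7 in ih_DCTC, with 0 genes called between them by edgeR. MHC class I genes were 0 higher and 3 lower of 12 (0 and 5 adjusted over the list alone), camera adjusted p = 0.00838, adjusted p = 0.568 with an estimated correlation. The immunoproteasome gene Psmb8 was at 3.31 ± 1.36 against 22.8 CPM. Thy1 was 183-fold (95% interval 62.5 to 887) lower than a mean that ih_CTC carried, at 50.5 ± 14.9 CPM, where C12, ih_DCTC and ih_STC_BM were at 1.85 ± 0.0366, 1.88 ± 2.61 and 0.232 ± 0.0797. These genes had an edgeR adjusted p of at most 0.0035. Csf1r was at 0.419 ± 0.0394 against 2.99 CPM (edgeR adjusted p = 0.0158), and the call of Csf1r in ih_BCTC against the other 4 lines ended without ih_BCTC 1, ih_BCTC 2 or ih_BCTC 3, with an adjusted p from 0.0648 to 0.10. Cdkn2a was at or under the floor of 3 counts in both, and Ptprc, Itgam, Col1a1, Pdgfrb, Mki67, Cd274 and Myc did not pass (edgeR adjusted p at least 0.113). Cd274 passed without the libraries of low intron share (adjusted p = 0.00444), and Mki67 without ih_DCTC 2 (adjusted p = 0.00928).

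Cells in a dish meet only tumour cells, those in a xenograft also host tissue and vessels. C12 and ih_CTC are both labelled as macrophages, one from each setting, and comparing them asks what the setting changed. The setting cannot be told apart from other differences between these lines, such as sex: C12 carried Xist and ih_CTC Y-linked Uty and Kdm5d. C12 had 1514 genes higher and 1089 lower than ih_CTC. The number of genes changed in C12 against ih_CTC, 2603, became 1550, 1301 and 4608 without C12 1, 2 and 3, and 1480 and 1317 without ih_CTC 1 and 2. Higher in C12 were Slurp1 (ENSMUSG00000022596, chromosome 15, 74724318 to 74728034), a secreted skin protein gene, 853-fold (95% interval 153 to 33752), the phosphoglucomutase-like gene Pgm5 at 57.1 ± 31.9 against 0.14 ± 0.13 CPM, and the carboxylesterase gene Ces1f, 291-fold (95% interval 99.3 to 1415). Lower in C12 were the calcium-regulating hormone gene Stc1 (ENSMUSG00000014813, chromosome 14, 69029289 to 69041401), 1484-fold (95% interval 266 to 58657), the cadherin gene Cdh11, 1189-fold (95% interval 213 to 47004), and the cholecystokinin gene Cck at 0.162 ± 0.0553 against 141 ± 18.2 CPM. Pan-leukocyte genes were 8 higher and 1 lower of 16 (9 and 1 adjusted over the list alone), camera adjusted p = 1.9e-04, adjusted p = 0.238 with an estimated correlation, at summed levels of 103 ± 21.4 and 34.1 ± 4.06 CPM, with Vav1 101-fold (95% interval 27.7 to 844) higher. MHC class I genes were 6 higher and 0 lower of 12 (6 and 0 adjusted over the list alone), camera adjusted p = 0.0236, adjusted p = 0.77 with an estimated correlation. With the intron share as a covariate the list was 3 higher and 1 lower. Psmb8 was at a log2 fold change of 2.08. The call of Psmb8 in C12 against ih_CTC ended with glmTreat and with the covariate (adjusted p = 0.0865 and 0.0902). MHC class II genes were 3 higher and 0 lower of 8 (3 and 0 adjusted over the list alone), camera adjusted p = 0.0563. Cd74 was at 13 ± 2.76 against 0.651 ± 0.284 CPM. Macrophage and monocyte genes were 3 higher and 2 lower of 20 (3 and 3 adjusted over the list alone), camera adjusted p = 0.55. The lysosomal gene Cd68 was at 46 ± 22 against 3.65 ± 1.46. Matrix genes were 2 higher and 4 lower of 20 (4 and 8 adjusted over the list alone), camera adjusted p = 0.484. Dcn was at 13.7 ± 16.8 against 679.6 ± 11.3 CPM, and Thy1 was at 1.85 ± 0.0366 against 50.5 ± 14.9. The genes named for C12 against ih_CTC so far had an edgeR adjusted p of at most 0.00967. Ptprc was higher at 0.758 ± 0.378 against 0.236 ± 0.0651 CPM (edgeR adjusted p = 0.0154), and the call of Ptprc in C12 against ih_CTC ended without C12 3 or ih_CTC 2, with an adjusted p from 0.0815 to 0.148. Csf1r, Itgam, Col1a1, Pdgfrb, Mki67, Cd274 and Myc did not pass (edgeR adjusted p at least 0.106). Mki67 passed in a fit of those groups (adjusted p = 0.0303). Without low-intron libraries only C12 3 was left, so no call is given.

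Dendritic cells and macrophages share an origin and many genes, but only dendritic cells specialise in starting T cell responses. Comparing ih_DCTC with the mean of C12 and ih_CTC asks whether lines labelled from each kept that difference. ih_DCTC had 1082 genes higher and 437 lower, and the number of genes changed in ih_DCTC against the macrophage lines, 1519, fell to 1009 without ih_DCTC 3. Dendritic cell genes were 3 higher and 0 lower of 14 (3 and 0 adjusted over the list alone), camera adjusted p = 0.528. The dendritic factor gene Zbtb46 was at 6.13 ± 2.8 against 1.95 CPM. The highest genes included Nlrp2 (ENSMUSG00000035177, chromosome 7, 5298554 to 5351035) and Sox2, 1382-fold (95% interval 382 to 11423) and 1447-fold (95% interval 494 to 7022) higher. The lowest included the X-linked gene Armcx2 (ENSMUSG00000033436, chromosome X, 134804145 to 134809221), 1369-fold (95% interval 379 to 11303), and the renin-binding protein gene Renbp, 447-fold (95% interval 124 to 3692). Neuron genes were 4 higher and 0 lower of 9 (5 and 0 adjusted over the list alone), camera adjusted p = 0.0069, adjusted p = 0.225 with an estimated correlation. Stmn2 was at 83.9 ± 36.7 against 0.90 CPM. Pan-leukocyte genes were 0 higher and 6 lower of 16 (0 and 7 adjusted over the list alone), camera adjusted p = 1.8e-04, adjusted p = 0.225 with an estimated correlation. Itgb2 was at 4.54 ± 2.19 against 36.8 CPM. The cytokine genes Il6 and Csf3 were at 113 ± 152 against 11.1 and 38 ± 32.4 against 2.45 CPM, in lists with 3 higher and 0 lower of 15 and 3 higher and 0 lower of 17. The edgeR adjusted p of these genes was at most 0.00684. Cell cycle genes were 0 higher and 0 lower of 22 (0 and 0 adjusted over the list alone) by edgeR, while camera ranked the list lower, camera adjusted p = 0.00197, adjusted p = 0.875 with an estimated correlation. Glycolysis genes were 2 higher and 0 lower of 14 (2 and 0 adjusted over the list alone), camera adjusted p = 0.00591, adjusted p = 0.875 with an estimated correlation, and 6 higher and 0 lower with the intron share as a covariate. Thy1 was at 1.88 ± 2.61 against 26.2 CPM, a mean of 1.85 ± 0.0366 in C12 and 50.5 ± 14.9 in ih_CTC (edgeR adjusted p = 0.0203), and the call of Thy1 in ih_DCTC against the macrophage lines ended without ih_DCTC 1 or ih_DCTC 2, with an adjusted p from 0.0616 to 0.0831. Ptprc, Csf1r, Itgam, Col1a1, Pdgfrb, Mki67, Cd274 and Myc did not pass (edgeR adjusted p at least 0.361), but Cd274 passed without the libraries of low intron share (adjusted p = 0.0154). The glucose transporter gene Slc2a1 was at 1502 ± 1549.7 against 291 CPM (edgeR adjusted p = 0.00825), and the call of Slc2a1 in ih_DCTC against the macrophage lines ended without ih_DCTC 1, with an adjusted p = 0.243.

 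A pair of lines with a shared origin would lie close together, so each pair was compared. A test of ih_DCTC against ih_BCTC, added after the data were seen, called 0 genes by edgeR, with 1605 genes at an unadjusted p under 0.05, while DESeq2 called 116 and limma-voom 0. The other 9 pairs of lines, of which C12 against ih_CTC was planned, differed in 992 to 3212 genes by edgeR. Without ih_DCTC 2 the number of genes changed in ih_DCTC against ih_BCTC was 490, and without ih_BCTC 2 it was 1. The library ih_DCTC 2 lay 0.459 to 0.545 from the ih_BCTC libraries in profile distance, nearer than to the other ih_DCTC libraries, at 0.873 and 1.10.

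**Figure D5:**
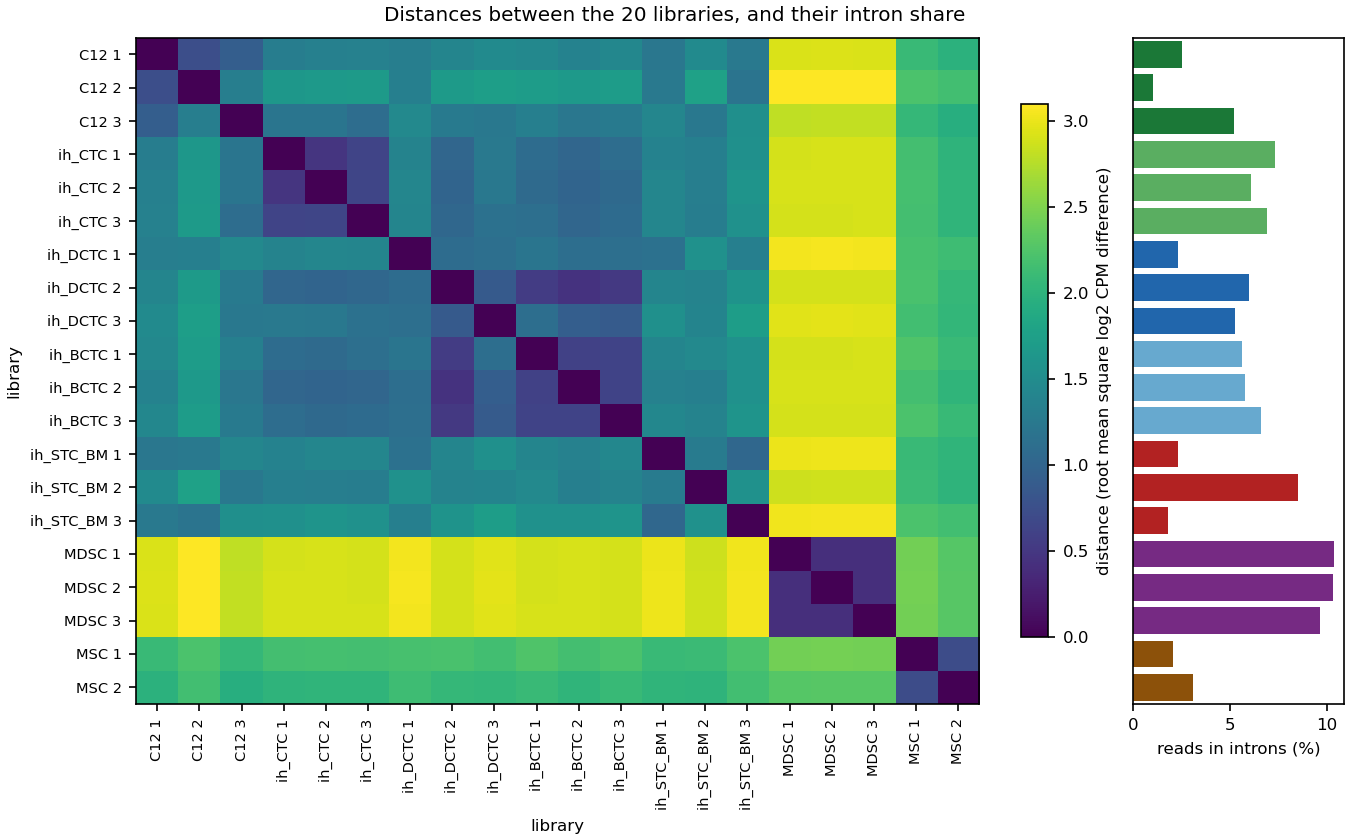
Left, root mean square log2 CPM difference between each pair of the 20 libraries, from 0 in dark blue to above 3 in yellow. Right, the share of each library's reads in introns, in percent, by group; ih_DCTC 2 lies 0.459 to 0.545 from the ih_BCTC libraries.

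Myeloid-derived suppressor cells are immature granulocytes and monocytes, and mesenchymal stem cells are stromal. Comparing MDSC with MSC measures how far apart these groups lie and which cells they hold. MDSC had 3212 genes higher and 4047 lower than MSC. Granulocyte genes were 18 higher and 0 lower of 18 (18 and 0 adjusted over the list alone), camera adjusted p = 2.8e-15. The neutrophil marker gene Ly6g was 2211-fold (95% interval 397 to 87374) higher. Erythroid genes were 8 higher and 0 lower of 8 (8 and 0 adjusted over the list alone), camera adjusted p = 7.7e-10, and lymphocyte genes 11 higher and 1 lower of 12 (11 and 1 adjusted over the list alone), camera adjusted p = 1.7e-08. MHC class II genes were 8 higher and 0 lower of 8 (8 and 0 adjusted over the list alone), camera adjusted p = 1.9e-07. The highest genes included Alas2 (ENSMUSG00000025270, chromosome X, 150547375 to 150570638), at least 2755-fold higher, and the anion exchanger gene Slc4a1, 24739.9-fold (95% interval 4440.0 to 977204) higher. The T cell gene Cd3d was at least 186-fold higher, the class II regulator gene Ciita at 107 ± 1.35 against 0.384 ± 0.0462 CPM, and the homing receptor gene Ccr7 at 699.5 ± 10.6 against 0.348 ± 0.244. Ighm (ENSMUSG00000076617), chosen after its values were seen, was at 37094 ± 930.5 CPM in MDSC and 347 ± 408 in MSC. The lowest were the Wnt agonist gene Rspo2 (ENSMUSG00000051920, chromosome 15, 43020811 to 43170818), the matrix gene Fmod and Dclk1, all with 0 counts in MDSC and at least 967-fold, 798-fold and 576-fold lower. Matrix genes were 0 higher and 18 lower of 20 (0 and 18 adjusted over the list alone), camera adjusted p = 7.7e-10, adjusted p = 0.151 with an estimated correlation. Smooth muscle genes were 0 higher and 9 lower of 9 (0 and 9 adjusted over the list alone), camera adjusted p = 1.1e-07. Col1a1 was at 2.51 ± 0.223 against 2077 ± 182 CPM and Col5a2 at 0.557 ± 0.285 against 779 ± 12. Macrophage and monocyte genes were 4 higher and 13 lower of 20 (5 and 14 adjusted over the list alone), camera adjusted p = 0.0080, adjusted p = 0.314 with an estimated correlation. The scavenger receptor gene Marco was at 0.611 ± 0.486 against 35.1 ± 36.9 CPM and Csf1r at 221 ± 2.21 against 981 ± 55.1. Ptprc was at 1556 ± 28.9 against 214 ± 32.2 CPM, and pan-leukocyte genes were 5 higher and 2 lower of 16 (5 and 2 adjusted over the list alone), camera adjusted p = 0.237. Thy1, Cd274 and Myc were higher and Pdgfrb and Cdkn2a lower, at log2 fold changes of 3.92, 2.92, 2.50, -5.93 and -6.46, and Mki67 did not pass (edgeR adjusted p = 0.0671). Mki67 in MDSC against MSC passed with DESeq2, limma-voom and a fit of those groups (adjusted p = 0.0159, 0.0418 and 0.00262). The call of Itgam in MDSC against MSC (edgeR adjusted p = 0.0255) ended without MDSC 1, MDSC 2, MSC 1 or MSC 2, with an adjusted p from 0.0505 to 0.201, and that of Itgax (edgeR adjusted p = 0.00771) without MSC 1, with an adjusted p = 0.725. The intron share was about 10% in MDSC and 2% to 3% in MSC, and with it as a covariate the calls of Ptprc, Ly6g, Cd3d, Thy1, Cd274, Csf1r, Marco, Fmod, Itgam and Itgax ended, with an adjusted p from 0.0567 (Fmod in MDSC against MSC) to 0.809 (Itgax in MDSC against MSC), and lymphocyte genes were 4 higher and 1 lower and macrophage and monocyte genes 1 higher and 9 lower. Csf1r, Itgam and Itgax also ended with the MDSC libraries summed to 1. Immediate early genes were 7 higher and 0 lower of 10 (7 and 0 adjusted over the list alone), camera adjusted p = 0.00486, adjusted p = 0.464 with an estimated correlation. Fosb was at 2029 ± 41.1 against 1.18 ± 0.546 CPM. For the other genes that passed the edgeR adjusted p was at most 0.00883.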

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

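The tests of scaling, of 1 cell line behind all labels, of a hiding effect of the intron share, of other splits of ih_DCTC against ih_BCTC and those with the lines kept as groups were chosen after the results were seen. The change from the precursor differed between ih_STC_BM and the mean of the 3 myeloid-labelled lines in 4715 genes by an edgeR interaction test, 1963 with a higher and 2752 with a lower value in ih_STC_BM. The precursor groups themselves differed in 7259 genes, so this count measures MDSC against MSC as well as the lines. In data the comparisons did not use, the share of reads between genes that carry a deletion was 0.26% in C12 1, 0.55% in ih_CTC 1 and 0.18% in ih_CTC 3, against at most 0.08% in the MDSC and MSC libraries. The same 3 libraries had the highest levels of the long noncoding gene Yam1, at 17483, 42746 and 10792 CPM, and ih_CTC 1 had the lowest mapped share, 67.4%. Yam1 (ENSMUSG00000098178) was chosen after its values were seen, and leaving it out changed no call of a named gene.

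Leukocyte genes lay far below MDSC in all 5 lines, although 3 are labelled as macrophages or dendritic cells: summed pan-leukocyte levels were 7.74 to 103 CPM over the lines and 9584 in MDSC. Scaling is excluded: over unscaled CPM the median log2 ratio of the pan-leukocyte genes, lines over MDSC, was -8.83, and scaling factors of any pair of libraries differed by at most 0.62 on the log2 scale. A single line behind all labels is argued against. The 6 ih_CTC and ih_STC_BM libraries had Uty and Kdm5d with Xist at most 1.48 CPM. Also Y-linked, Ddx3y and Eif2s3y were 0 in ih_CTC. The other 9 had Xist at 30.1 CPM or more and no Uty or Kdm5d. A trace of myeloid origin stays open: the list did not differ between the 3 myeloid-labelled lines and ih_STC_BM with an estimated correlation (camera p = 0.725), with 0 of 16 genes higher and 3 lower. Loss of the leukocyte programme on transformation and an origin from mesenchymal host cells could each give such values, and the study has no lineage mark that was analysed here.

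By edgeR, 0 genes changed in ih_DCTC against ih_BCTC (1605 at an unadjusted p under 0.05, 116 by DESeq2 and 0 by limma-voom), but without ih_DCTC 2 the number was 490. Only ih_DCTC 2 lay close to the ih_BCTC libraries in profile distance, at 0.459 to 0.545, against 1.11 to 1.2 for ih_DCTC 1 and 0.883 to 1.11 for ih_DCTC 3. Hiding by intron share stays open. With that share as covariate or without ih_DCTC 1 the count was 0, but both fits kept ih_DCTC 2. A mislabelled ih_DCTC 2 stays open: on genes higher in ih_BCTC than in the other lines, ih_DCTC 2 lay on the ih_BCTC side for 97.3%, ih_DCTC 1 for 55.2% and ih_DCTC 3 for 78.7%, while libraries of the other lines lay between 22.3% and 69.3%. Gene sets differed, with 800 genes for C12, 817 for ih_STC_BM and 1934 for ih_CTC and means over these 3 sets for ih_DCTC, so the shares are not of the same genes. A shared source of both lines could also give few calls, and that was not tested.

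Libraries within a line spread along their intron share, with C12, ih_DCTC and ih_STC_BM each holding libraries under 3% and above 5%. Sequencing depth is argued against: with log2 total count in the model, 88.1% of the genes called for the intron share stayed called. The intron share had a coefficient past the threshold in 6031 of 13832 genes over the 15 line libraries, against at most 6005 and a median of 0 in 99 permutations within lines, so 1 of 100 draws, the real one, reached it. Growth state of the cultures stays open: 10 of 22 cell cycle genes fell and 0 rose as the share rose, with camera p = 0.381 at an estimated correlation and 5.8e-04 at the preset one. RNA quality or the making of the libraries may also set the share, and neither was tested.

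Other splits of the libraries into groups of the same sizes were counted. For 3 libraries against 3 only 10 splits exist, too few for a share under 0.05. There, C12 against MDSC, ih_CTC against MDSC, ih_DCTC against MDSC and C12 against ih_CTC called 9354, 11335, 8920 and 2172 genes in fits of those libraries alone, the most of 10 splits in each case (1 split, the real one), with 0 in every other split. For ih_DCTC against ih_BCTC the real count was 0, which any split reaches, so all 10 did, the highest other being 0. Genes higher and lower in all 3 myeloid-labelled lines were 3572 and 3322. The 99 other draws of the 4 groups gave at most 233 and 96, but mix MDSC with lines and cannot test sharing. For ih_DCTC against the macrophage lines, 3 of 84 splits called as many as the real 291, and the highest, 4571, set ih_DCTC 1, C12 1 and C12 2 apart, which are the libraries of low intron share in those lines. With the lines kept as groups, 1 of 100 draws reached the real 981, the highest other being 761. For ih_BCTC against the other lines, a fit with 2 groups called 0 genes, reached by 100 of 100 draws (highest other 3), so that fit does not exclude chance. With the lines kept as groups, 3 of 100 draws reached the real 818, and the highest, 3756, set C12 1, C12 2 and ih_STC_BM 3 apart, again libraries of low intron share. With the intron share as a covariate, there were 2568 genes changed in ih_DCTC against the macrophage lines and 1890 genes changed in ih_BCTC against the other 4 lines in the fit of all libraries.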

How the results depend on the processing

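The alternatives with the intron share, the low-intron libraries, Yam1 and summed MDSC libraries, and every value for ih_DCTC against ih_BCTC, were chosen after the results were seen. The counts against MDSC stayed within 1.5 times their main values under every alternative tried, from 6766 to 10087 in C12, 5881 to 11335 in ih_CTC and 6284 to 11127 in ih_DCTC, and from 8698 to 10142, 7628 to 7970 and 8173 to 9050 with 1 library left out. Genes lower in all 3 lines also stayed within it, from 2483 to 4034. Scaling, the filter, limma-voom, an added log2 limit of 1 and leaving out Yam1 moved none of the counts tried by over 1.5 times; the counts shared by the 3 lines were not tried with upper quartile scaling or limma-voom.

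Counts that moved by more did so as follows. For genes changed in ih_STC_BM against MSC (main 5066) the count was 1904 in a fit of those groups, 2708 with glmTreat and 7971 with the intron share as a covariate. For genes changed in ih_BCTC against the other 4 lines (main 1361) it was 2150 with DESeq2, 818 in a fit of the lines alone, 337 with glmTreat and 3486 without the low-intron libraries. For genes changed in C12 against ih_CTC (main 2603) it was 789 with glmTreat. For genes changed in ih_DCTC against the macrophage lines (main 1519) it was 981, 599 and 2568 with those groups alone, glmTreat and the covariate. For genes changed in MDSC against MSC (main 7259) it was 11072 and 4443 with those groups alone and glmTreat, and 4088 with the MDSC libraries summed. For genes changed in ih_DCTC against ih_BCTC (main 0) it was 116 with DESeq2. Genes higher in all 3 lines than in MDSC (main 3328) fell to 1912 with the MDSC libraries summed. glmTreat asks for a change above 1 on the log2 scale; for the other moves the cause was not tested. With 1 library left out the counts ranged from 3120 to 6147 in ih_STC_BM against MSC, lowest without MSC 1, from 524 to 2047 in ih_BCTC, lowest without ih_BCTC 1 and highest without ih_STC_BM 2, and from 1301 to 4608 in C12 against ih_CTC, lowest without C12 2 and highest without C12 3. They ranged from 1009 to 1666 in ih_DCTC against the macrophage lines, lowest without ih_DCTC 3, and from 0 to 490 in ih_DCTC against ih_BCTC, highest without ih_DCTC 2.

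The distance to MDSC minus that to MSC stayed above 0 in every setting and line. In the order C12, ih_CTC, ih_DCTC, ih_STC_BM and ih_BCTC it was 2.09, 2.13, 2.14, 2.12 and 2.07 over the 2000 genes of largest variance, and 1.01, 0.97, 0.996, 1.03 and 0.92 with a prior count of 0.5, which weigh changed and low genes more. It was 0.84 with RLE scaling in ih_CTC, and ranged with 1 library left out from 0.78 to 0.91, 0.70 to 0.85, 0.75 to 0.89, 0.80 to 0.93 and 0.66 to 0.80, lowest without MSC 2 in each line.

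Of 232 gene list tests, 75 passed with camera at the preset correlation, 30 at the estimated one and 126 with fry, which asks a different question; RLE scaling passed the same number, 75. The p53 pathway list in ih_STC_BM against MSC passed with fry in the other direction (adjusted p = 0.00386), and it did not pass with camera. Named genes kept their direction and side of the threshold in 221 of 222 cases with RLE, 222 of 222 with upper quartile scaling, 220 of 222 without the filter, 215 of 218 with DESeq2, 220 of 222 with limma-voom, 204 of 212 with the compared groups alone and 208 of 222 with glmTreat. They did in 1460 of 1498 with 1 library left out, 201 of 222 with the covariate, 156 of 164 without the low-intron libraries and 130 of 135 with the MDSC libraries summed. The sign reversed with the covariate for Plk1 in C12 against MDSC (from 1.63 to -0.50, and to -0.66 without the low-intron libraries), Tpi1 in C12 against MDSC (from 2.96 to -0.40) and Eno1 in C12 against MDSC (from 2.76 to -0.12); the cause was not tested. Depth limits genes at or under the floor of 3 counts, such as Olig2 and, between lines, Cdkn2a. The simulations above changed few genes, so their missed 2-fold changes need not carry over.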

Other observations

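The test of a deletion of Cdkn2a and Cdkn2b, the genes singled out here and the limits of 20 and 1 CPM were chosen after the results were seen. By those limits, 9 genes were above 20 CPM in each of the 15 line libraries and under 1 CPM in each of the 5 precursor libraries, and 67 were the reverse. Among the 9 were the homeobox gene Rhox5 (ENSMUSG00000095180) and Msln, with medians over the lines of 258 and 123 CPM. Among the 67 was the chemokine receptor gene Cxcr4 (ENSMUSG00000045382), at most 0.74 CPM in the lines and at least 109 in the precursor libraries. The 3 MDSC libraries differed from each other by a chi-square of 1.72 to 3.32 per gene, where pairs within the other groups gave 25.6 to 282, and none of the libraries were identical. With the MDSC libraries summed to 1, there were 6771 genes changed in C12 against MDSC, 5937 genes changed in ih_CTC against MDSC and 6284 genes changed in ih_DCTC against MDSC.

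Cdkn2a and its neighbour Cdkn2b, inhibitors whose loss lets many cultured cells divide without limit, had 1 and 2 counts summed over the 15 line libraries, against 440 and 670 in the 2 MSC libraries and 6 and 16 in the 3 MDSC libraries. Adjacent Mtap (ENSMUSG00000062937) had 70808 counts in lines (156 to 657 CPM), 993 in MSC and 285 in MDSC. A deletion of Cdkn2a and Cdkn2b stays open: the larger summed count, 2, was known when the test was chosen and decides nothing. Silencing of both could give the same counts and was not tested.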
